A study of Mus musculus with 20 samples.

How the data were processed

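Kidney RNA from normal and Hyp mice on control or low phosphate diet was measured on 20 arrays, each a pool from 3 mice per the labels. The deposited table held 1 intensity per probe set and array on a linear scale, which the authors had scaled so that the mean after trimming 2% at each end was the same on every array (500.254 to 500.309). The software the authors used is not given in the sources used here. Array medians ran from 185.75 to 228.15, and 0 columns of per-sample values were left unused. No pair of arrays was identical. The deposited values carry no read depth or background estimate, so the number of arrays sets the precision. P-values measure the spread between pools of 3 mice, not between single mice.

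The table held 12488 probe sets. The 66 control probe sets were set aside and examined on their own, which left 12422. Of these, 10833 name 1 gene, 396 name several and 1193 name none. Symbols were compared with the mouse RefSeq gene table by gene number, which matched 10817 of the probe sets with 1 gene and changed 0 symbols. Intensities were not rescaled. An offset of 38, the 20th percentile of all values, was added before taking log2, so a log2 difference understates the fold change of a dim gene. Probe sets whose mean intensity lay below the 30th percentile were left out, which left 8695 for testing.

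Each comparison was fitted with limma 3.58.1 in R 4.3.3 on all 20 arrays, with the 4 groups and the 4 strata of sex and days as terms and 13 residual degrees of freedom, followed by empirical Bayes moderation. Two-sided p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The 5 main comparisons were diet in each genotype, genotype on each diet and the genotype by diet interaction. The rest of the 12 comparisons were diet averaged over genotypes, genotype averaged over diets, sex, days, diet by sex, genotype by sex and diet by days. Gene lists for kidney segments, other cell types, transport, metabolism and stress were tested with limma's camera at a preset correlation of 0.01, with 1 probe set per gene (the brightest; 6439 genes) and at least 5 measured genes per list. Of 38 lists 37 were tested, the list of Y-linked genes being too small, and the test was repeated with a correlation estimated for each list. Member counts are given over all probe sets tested and adjusted over the list alone.

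In each main comparison the genes named were the 10 with the largest rise and the 10 with the largest fall among those past the threshold, with 1 gene per probe set and the same sign in all 4 strata, or all of them where fewer passed. In the averaged comparisons and for sex and days they were 5 in each direction without the strata rule, and where no probe set passed they were the 3 with the smallest p in each direction. A set of 14 genes of phosphate and vitamin D handling was always examined, where measured, and 4 members of each called list. Slc34a3 and Slc20a2 were not analysed here. A gene with several probe sets is given by the brightest. The groups, lists, comparisons, named-gene rule and the first set of alternatives below were chosen before the data were examined.

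The alternatives tried were an offset of 1, quantile normalization, no intensity filter, a filter at the median, moderation with a trend and robust variances, no terms for sex and days, a fit to the 2 groups compared, fits within each sex and each duration, and each array left out in turn. For lists, they were an estimated correlation and the mean of a gene's probe sets. Added after the data were seen were the array set as a block (6 sets by title number, 01 to 04, 05 to 08, 09 and 10, 11 to 14, 15 to 18, and 19 and 20), array weights, and fits without arrays 05 to 08 or without arrays 09, 10, 19 and 20. For every comparison, 100 splits of the arrays into groups of the same sizes, the real one included, were compared. For the 7 diet and genotype comparisons, splits that keep each group's number of arrays in every stratum of sex and days were added after the others had been seen, all 24 of them in the comparisons of 2 groups and 100 drawn from 1152 in the others.

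The steps were checked on simulated data with 200 changed probe sets among 8695 in each of 12 draws. In the comparison of diets in normal mice, 34.8% of probe sets changed by 0.5 and 83.2% of those changed by 1 on the log2 scale were recovered, and 3.28% of calls were false. For the interaction the values were 7.92%, 56.7% and 5.83%, and for genotype averaged over diets 64.6%, 96.2% and 5.35%. Lists of 20 genes moved by 0.3 had an unadjusted camera p under 0.05 in 12 of 12 draws, and unmoved lists in 0. In the wrong direction 0 probe sets were called. The simulated noise was independent between probe sets and held no array sets beyond the strata of sex and days. It therefore cannot show how often lists of genes that vary together are called without a shift. With fewer true changes than the 200 in each draw, the adjusted threshold is stricter and recovery would be lower.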

Results

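RNA from mouse kidney was measured on 20 oligonucleotide arrays, each hybridised with a pool from 3 mice, to ask how the kidney responds to a low phosphate diet and whether Hyp mice respond in the same way. Hyp mice carry a mutation of Phex and are a model of X-linked hypophosphatemia, a disorder of renal phosphate wasting. The 4 groups were normal mice on control diet, normal mice on low phosphate diet, Hyp mice on control diet and Hyp mice on low phosphate diet, with 5 arrays in each. Of the 20 arrays, 12 came from males and 8 from females, and 12 came from mice fed for 5 days and 8 from mice fed for 3 days. Values were signal intensities that the authors had scaled to a common trimmed mean, which ran from 500.254 to 500.309, and the number of arrays limited the precision. Differences are given on the log2 scale with the standard error (SE) of the limma fit, and "higher in Hyp" means higher than in normal mice.

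Phex, the gene affected in Hyp mice, was dim in every group. Its intensity was 36.9 ± 19.9 (SD, n = 5) in normal mice on control diet and 24.6 ± 11.6 (SD, n = 5) in Hyp mice on control diet. On low phosphate diet it was 44.9 ± 27.0 (SD, n = 5) and 62.3 ± 31.1 (SD, n = 5), and the gene lay below the intensity filter, so it was not tested. Whether its probe set lies in the part of the gene lost in Hyp is not known here, so its level checks nothing about genotype. Xist, transcribed from the inactive X chromosome, ran from 1306 to 1913 in the 8 female arrays and from 6.1 to 60.9 in the 12 male arrays. Eif2s3y, a Y-linked gene, ran from 156 to 382 in male and from 1.7 to 91.1 in female arrays, so every array matched its sex label. The 20 arrays differed in quality. The 4 arrays numbered 05 to 08, all female mice at 5 days with 1 array per group, had median Spearman correlations with the other arrays of 0.895 to 0.934, and arrays 01 to 04 had 0.958 to 0.962. Their actin 3′ to 5′ intensity ratios, a sign of RNA quality, were 1.74 to 2.61, those of arrays 01 to 04 were 1.22 to 1.27 and those of the other 12 arrays were 1.39 to 1.98. Within sets of arrays that share a sex, a duration and a run of title numbers, the diet and genotype groups could be compared 4 times, once in each combination of sex and days.

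**Figure D1:**
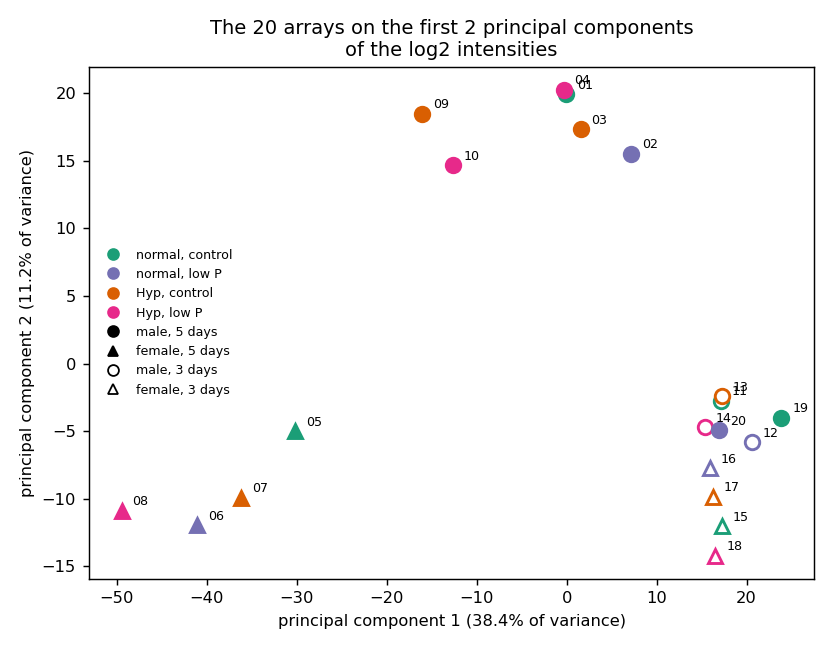
Principal components 1 (38.4% of variance) and 2 (11.2% of variance) of the log2 intensities, 1 point per array, with colour for diet and genotype, shape for sex and fill for days. Arrays 05 to 08 lie at -49.4 to -30.1 on component 1, and arrays 19 and 20, from 5-day males, lie with the 3-day arrays on the right.

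The response of normal mice to low phosphate was compared between 5 arrays on each diet. Acot1, an acyl-CoA thioesterase induced through PPAR alpha, rose from an intensity of 974.6 ± 156 to 1960 ± 138 (SD, n = 5 each). Mdk, the growth factor midkine, rose from 626 ± 140 to 1245 ± 264, and Retsat, retinol saturase, rose from 1199 ± 310 to 2133 ± 312 (SD, n = 5 each). Ces1d, a carboxylesterase, fell from 3857 ± 699 to 1742 ± 408 (SD, n = 5 each). Ttr, the thyroid hormone and retinol carrier transthyretin, fell from 434 ± 51.0 to 161 ± 40.5 (SD, n = 5 each). The collagen chains Col5a2 (log2 difference -0.71 ± 0.12 SE) and Col15a1 (-0.86 ± 0.17 SE) also fell, as did Glud1, the mitochondrial glutamate dehydrogenase (-0.63 ± 0.11 SE), and Odc1, the first enzyme of polyamine synthesis (-0.97 ± 0.18 SE). In limma, 16 of 8695 probe sets passed an adjusted p of 0.05, 8 higher and 8 lower, and 747 had an unadjusted p under 0.05. The log2 differences were -1.14 for Ces1d (adjusted p = 0.00027), -1.27 for Ttr (adjusted p = 0.0026), 0.99 for Acot1 (adjusted p = 0.0084), 0.95 for Mdk and 0.83 for Retsat (adjusted p = 0.013 for both), each with the same sign in all 4 combinations of sex and days. The rule for naming genes selects for this agreement in sign, so it is no separate support. Genes of the vitamin D and phosphate axes did not pass in normal mice. Cyp27b1, the renal enzyme that makes active vitamin D, had 280 ± 46.6 on control and 499 ± 131 on low phosphate diet (SD, n = 5 each), a log2 difference of 0.73 (adjusted p = 0.33). The sodium-phosphate cotransporter gene Slc34a1 differed by 0.18 (adjusted p = 0.73), Kl, which encodes the FGF23 co-receptor klotho, by 0.20 (adjusted p = 0.64), and S100g, a vitamin D-dependent calbindin, by 0.47 (adjusted p = 0.34).

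Of 37 gene lists tested with camera, 10 differed by diet in normal mice, and none of these calls held with an estimated correlation. Among 30 fatty acid oxidation and PPAR alpha genes, which were higher as a list (mean log2 difference 0.27, adjusted p = 1.0e-05; adjusted p = 0.24 with an estimated correlation), Acot1 alone rose over all probe sets tested. Adjusted over the list alone, 6 rose, namely Acot1, Cyp4a14, Angptl4, Slc25a20, Cyp4a10 and Pdk4. The extracellular matrix list of 35 genes was lower (mean -0.21, adjusted p = 3.0e-06; adjusted p = 0.22 with an estimated correlation). Its members Col5a2 and Col15a1 fell over all probe sets, and 11 members fell adjusted over the list alone. Cholesterol synthesis genes, 16 measured, were lower (mean -0.24, adjusted p = 0.00017; adjusted p = 0.13 with an estimated correlation). Of the 16, 13 had a negative sign. None of them passed over all probe sets and 5 fell adjusted over the list alone, Mvd, Msmo1, Nsdhl, Cyp51 and Ebp. Within the 4 array sets that hold both diets and genotypes, the mean shift was 0.12 to 0.45 for fatty acid oxidation. It was -0.42 to -0.11 for extracellular matrix and -0.32 to -0.21 for cholesterol synthesis, while arrays 11 to 14 gave -0.012 for glucocorticoid-responsive genes and arrays 01 to 04 gave -0.013 for ribosomal proteins, against the direction of those lists. Endoplasmic reticulum stress genes were lower (24 measured, adjusted p = 0.0029; adjusted p = 0.13 with an estimated correlation). The chaperone genes Manf and Hspa5 fell adjusted over the list alone, and 0 of the 24 over all probe sets in limma. Glucocorticoid-responsive genes were higher as a list (19 measured, adjusted p = 0.037; adjusted p = 0.44 with an estimated correlation). Adjusted over the list alone Angptl4, Sgk1, Pdk4 and Zbtb16 rose and Pck1 fell, against 0 over all probe sets, and the list's call was lost with the array set as a block (adjusted p = 0.0502). Kidney genes known to be higher in males were lower on low phosphate diet (14 measured, mean -0.30, adjusted p = 0.0089; adjusted p = 0.36 with an estimated correlation). Of these, Odc1 fell over all probe sets and 4 fell adjusted over the list alone, Odc1, Gsta2, Slc22a6 and Cyp4b1. Endothelial markers were lower (12 measured, mean -0.17, adjusted p = 0.0063; adjusted p = 0.20 with an estimated correlation) beside the matrix genes. The respiratory chain (adjusted p = 0.0037; 0.46 as the adjusted p with an estimated correlation) and the proteasome (adjusted p = 0.034; 0.42 as the adjusted p with an estimated correlation) were lower. Ribosomal protein genes were higher (adjusted p = 0.0089; adjusted p = 0.29 with an estimated correlation). None of the members of these lists passed limma over all probe sets or adjusted over the list alone. Blocking on array set gave 58 probe sets, including all 16, but without arrays 05 to 08 there were 6 and without arrays 09, 10, 19 and 20 there were 8. Ces1d, Ttr and Acot1 kept their calls when each array was left out in turn, but Mdk lost its call without array 02 or 15 and Retsat without array 02, 06 or 11. Col15a1 lost its call for 16 of the 20 arrays, Odc1 for 13, Col5a2 for 7 and Glud1 for 6. The count of 16 fell to 5 without array 02.

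In Hyp mice, the comparison asked how the same diet acts where phosphate is already being lost. On low phosphate diet S100g, a calcium-binding protein of the distal tubule, had the largest fall among called genes. It went from 3612 ± 1277 to 849 ± 299.8 and Calb1, the larger calbindin, from 4192 ± 538 to 1815 ± 85.5 (SD, n = 5 each). Cyp27b1 fell from 283 ± 156 to 88.7 ± 37.1 and Ttr from 3437 ± 903 to 1107 ± 244 (SD, n = 5 each). Pck1, the cytosolic phosphoenolpyruvate carboxykinase of gluconeogenesis, fell from 6127 ± 1654 to 3148 ± 1120, and Slc2a2, the basolateral glucose transporter, rose from 2170 ± 122 to 3134 ± 144 (SD, n = 5 each). Gbp7, an interferon-inducible guanylate-binding protein (log2 difference -0.94 ± 0.15 SE), Gldc of the glycine cleavage system (-0.69) and Col5a2 (-0.68) fell as well. In limma 13 probe sets passed, 3 higher and 10 lower, with 400 at an unadjusted p under 0.05. The log2 differences were -2.03 for S100g (adjusted p = 3.5e-06), -1.18 for Calb1 (adjusted p = 1.2e-05), -1.58 for Ttr (adjusted p = 0.00014), -0.98 for Pck1 (adjusted p = 0.015) and 0.52 for Slc2a2 (adjusted p = 0.025), each with the same sign in all 4 combinations of sex and days. Outside the always examined genes, the rule for naming selects for this agreement in sign. Cyp27b1 differed by -1.28 ± 0.24 SE (adjusted p = 0.043; 0.048 with the array set as a block). Cyp24a1, which degrades active vitamin D, had 1736 ± 565 and 3796 ± 2511 (SD, n = 5 each) and did not pass (0.91, adjusted p = 0.90).

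The vitamin D and calcium handling list, with 14 genes measured, was lower in Hyp mice on low phosphate diet (adjusted p = 0.0019; adjusted p = 0.063 with an estimated correlation). S100g, Calb1 and Cyp27b1 fell over all probe sets tested, and adjusted over the list alone these 3 fell and Cyp24a1 rose. The list's mean was -0.25 and its median -0.02, and its mean within the 4 array sets ran from -0.40 to -0.13. Interferon-responsive genes were lower (27 measured, mean -0.23, adjusted p = 7.6e-06; adjusted p = 0.50 with an estimated correlation), with 23 of 27 negative. None passed limma over all probe sets or adjusted over the list alone. Within array sets the mean of these genes ran from -0.75 in arrays 15 to 18 to -0.12 in arrays 11 to 14. Proteasome genes were lower (37 measured, adjusted p = 0.0011; adjusted p = 0.50 with an estimated correlation), 31 of them negative. The thick ascending limb and distal convoluted tubule list was lower (14 measured, adjusted p = 0.037; adjusted p = 0.35 with an estimated correlation). The extracellular matrix list was lower too (35 measured, adjusted p = 0.038; adjusted p = 0.65 with an estimated correlation). Calb1 alone of the tubule markers and Col5a2 alone of the matrix genes passed over all probe sets, and the tubule list lost its call with the array set as a block (adjusted p = 0.083). Adipocyte genes were higher (10 measured, adjusted p = 0.016; adjusted p = 0.50 with an estimated correlation). Within array sets the adipocyte mean was -0.0059 in arrays 05 to 08 and the matrix mean 0.032 in arrays 15 to 18, against the direction of those lists. Blocking on array set gave 14 probe sets, including all 13, and S100g, Calb1 and Ttr kept their calls without any single array. Gldc lost its call for 12 of the 20 arrays, Slc2a2 for 8, Col5a2 for 7, Pck1 for 5 and Gbp7 for 2. Cyp27b1 lost its call when any array but 02, 07 or 19 was left out, and the count of 13 ran down to 6 without array 13 or 14 and was 6 without arrays 05 to 08.

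Hyp and normal mice on control diet were compared to find the effect of genotype alone. Ttr was higher in Hyp, at 3437 ± 903 against 434 ± 51.0 in normal mice (SD, n = 5 each), and Dnase1, a secreted deoxyribonuclease, was lower, at 964 ± 306 against 4124 ± 1320 (SD, n = 5 each). Bex4 (1373 ± 154 against 785 ± 142), Pla2g7, the plasma platelet-activating factor acetylhydrolase (430 ± 67.2 against 220 ± 32.7), and Ier3, an immediate early gene (2400 ± 374 against 1302 ± 250, SD, n = 5 each), were higher in Hyp. Dusp6, the phosphatase of ERK kinases induced by FGF signalling, was 1258 ± 245 against 704 ± 104 (SD, n = 5 each). G6pc, the glucose-6-phosphatase catalytic subunit, was higher (log2 difference 0.59 ± 0.11 SE), and the glucose-6-phosphate transporter Slc37a4 (-0.56) and the glucose transporter Slc2a2 (-0.48 ± 0.09 SE) were lower. Limma called 21 probe sets, 13 higher and 8 lower, with 742 at an unadjusted p under 0.05. The log2 differences were 2.84 for Ttr (adjusted p = 5.1e-08), -2.07 for Dnase1 (adjusted p = 6.8e-06) and 0.79 for Bex4 (adjusted p = 0.0030). They were 0.86 for Pla2g7 (adjusted p = 0.0090), 0.87 for Ier3 (adjusted p = 0.0093) and 0.80 for Dusp6 (adjusted p = 0.026), with the same sign in all 4 combinations of sex and days. That agreement in sign is selected for by the rule for naming genes. Cyp24a1 was 1736 ± 565 in Hyp and 691 ± 446 in normal mice (SD, n = 5 each) and did not pass (1.46, adjusted p = 0.091). Cyp27b1 (-0.09, adjusted p = 0.94), Calb1 (-0.15, adjusted p = 0.71), Kl (-0.40, adjusted p = 0.23) and Slc34a1 (-0.26, adjusted p = 0.56) did not pass either.

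Interferon-responsive genes were higher in Hyp mice on control diet, 26 of 27 of them positive (mean 0.30, adjusted p = 1.3e-07; adjusted p = 0.25 with an estimated correlation). None passed limma over all probe sets or adjusted over the list alone, and the mean within array sets ran from 0.10 to 0.73. FGF and MAPK target genes were higher (8 measured, mean 0.29, adjusted p = 0.0049; adjusted p = 0.13 with an estimated correlation). Ier3 and Dusp6 passed over all probe sets and adjusted over the list alone, and the mean was 0.16 to 0.39 within array sets. Proximal tubule markers were lower (27 measured, adjusted p = 0.0066; adjusted p = 0.25 with an estimated correlation), among them Slc2a2, and had a mean of -0.13 to 0.031 within array sets. Beside these, macrophage and lymphocyte markers were higher (18 measured, adjusted p = 0.0049; adjusted p = 0.21 with an estimated correlation) with a mean within array sets of -0.0012 to 0.30. Red blood cell genes were higher (5 measured, adjusted p = 0.014; adjusted p = 0.21 with an estimated correlation), with Slc4a1 and Alas2 past the test adjusted over the list alone. Adipocyte genes were lower (10 measured, adjusted p = 0.016; adjusted p = 0.34 with an estimated correlation). The respiratory chain was lower (64 measured, adjusted p = 5.2e-06; adjusted p = 0.27 with an estimated correlation), with 50 negative and none past the test. Cholesterol synthesis was lower (adjusted p = 0.014; adjusted p = 0.25 with an estimated correlation), with Mvd past it over all probe sets. Among the array's control probe sets, the 5′ and middle 18S ribosomal RNA probe sets were lower in Hyp (-1.12 and -1.45, adjusted p = 0.0010 for both). Of the 21, 16 kept their calls with the array set as a block (20 in total), Ttr (2.78, adjusted p = 1.2e-06) and Dnase1 (-2.02) among them, while Slc2a2 and Car14 (adjusted p = 0.051 for both), G6pc (0.058) and Mvd (0.10) did not. Left out singly, 16 of the 20 arrays ended the call of Mvd, 12 that of G6pc, 10 that of Slc2a2, 8 that of Dusp6 and 7 that of Slc37a4. The count of 21 was 3 without arrays 05 to 08, 13 without arrays 09, 10, 19 and 20, and fell to 7 without array 13.

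On low phosphate diet, Hyp mice were set against normal mice to see genotype under phosphate restriction. The calbindins S100g (849 ± 299.8 in Hyp against 4617 ± 777) and Calb1 (1815 ± 85.5 against 4478 ± 476) were lower in Hyp (SD, n = 5 each). The enzymes of active vitamin D went in opposite directions, with Cyp27b1 lower in Hyp, at 88.7 ± 37.1 against 499 ± 131, and Cyp24a1 higher, at 3796 ± 2511 against 639 ± 142 (SD, n = 5 each). Kl was lower, at 4845 ± 631 against 7032 ± 474 (SD, n = 5 each). Ttr was higher and Dnase1 lower in Hyp, as on control diet. Slc26a1, a sulfate and anion exchanger of the proximal tubule, was lower (log2 difference -0.72 ± 0.11 SE). Psat1 of serine synthesis (log2 difference 0.75 ± 0.13 SE), Cyp4b1 (1.65 ± 0.31 SE), Hmox1, the inducible heme oxygenase (0.69 ± 0.14 SE), and Prom1 (0.74) were higher in Hyp. Limma called 31 probe sets, 18 higher and 13 lower, with 819 at an unadjusted p under 0.05. The log2 differences were -2.44 for S100g and 2.53 for Ttr (adjusted p = 1.6e-07 for both), -1.28 for Calb1 (adjusted p = 2.4e-06), -1.95 for Dnase1 (adjusted p = 8.9e-06) and -2.09 for Cyp27b1 (adjusted p = 0.00018). They were 2.25 for Cyp24a1 (adjusted p = 0.0020), -0.72 for Slc26a1 (adjusted p = 0.0031) and -0.54 for Kl (adjusted p = 0.037). All of these had the same sign in all 4 combinations of sex and days. For those outside the always examined genes, the rule for naming selects for this agreement. Within the 4 array sets Cyp27b1 ran from -2.31 to -1.81 and Cyp24a1 from 1.38 to 3.25. Slc34a1 (-0.40, adjusted p = 0.23) and Alpl, alkaline phosphatase (-0.72, adjusted p = 0.10), did not pass.

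Phosphate handling genes were lower in Hyp mice on low phosphate diet, 15 of 18 of them negative (mean -0.25, adjusted p = 8.1e-06; adjusted p = 0.012 with an estimated correlation). Kl alone passed the test over all probe sets, and Kl, Alpl, Slc34a1, Pth1r and Fgfr4 were lower adjusted over the list alone. Vitamin D and calcium handling genes were lower (14 measured, mean -0.33, adjusted p = 1.7e-05; adjusted p = 0.0085 with an estimated correlation). Of these, S100g, Calb1, Cyp27b1 and Kl were lower and Cyp24a1 higher over all probe sets, and Pth1r joined the lower ones adjusted over the list alone. The list means within array sets ran from -0.42 to -0.15 for phosphate handling and from -0.36 to -0.28 for vitamin D and calcium. FGF and MAPK targets were higher (8 measured, adjusted p = 0.0049; adjusted p = 0.055 with an estimated correlation), with Dusp6 past the test. Fatty acid oxidation genes were lower in Hyp, 28 of 30 of them negative (mean -0.25, adjusted p = 4.1e-06; adjusted p = 0.15 with an estimated correlation). In limma 0 passed over all probe sets, and Acot1 was the 1 past the test adjusted over the list alone. Their mean was -0.45 and -0.49 in the 5-day array sets 01 to 04 and 05 to 08, and -0.014 and -0.058 in the 3-day sets 11 to 14 and 15 to 18. Proximal tubule markers were lower (22 of 27 negative, adjusted p = 0.00024; adjusted p = 0.13 with an estimated correlation), although the member past the test over all probe sets, Cyp4b1, was higher in Hyp. Beside these, macrophage and lymphocyte markers were higher (17 of 18 positive, adjusted p = 0.0057; adjusted p = 0.13 with an estimated correlation), as were red blood cell genes (adjusted p = 0.013; adjusted p = 0.15 with an estimated correlation). Interferon-responsive genes (adjusted p = 0.0080; 0.53 as the adjusted p with an estimated correlation) and endoplasmic reticulum stress genes (adjusted p = 0.042; 0.15 as the adjusted p with an estimated correlation) were higher. Extracellular matrix genes were higher too (adjusted p = 0.012; adjusted p = 0.50 with an estimated correlation), Col5a2 among them. Respiratory chain (adjusted p = 0.0057; 0.50 as the adjusted p with an estimated correlation) and ribosomal protein genes (adjusted p = 0.0057; 0.20 as the adjusted p with an estimated correlation) were lower, with none past limma's threshold. The respiratory chain (adjusted p = 0.34) and matrix (adjusted p = 0.072) lists lost their calls with the array set as a block. Within array sets the mean of interferon-responsive genes was -0.043 to 0.32, of the respiratory chain -0.12 to 0.051 and of ribosomal proteins -0.15 to 0.026, so each changed sign in some set. With that block 38 probe sets passed, including 27 of the 31, and Hmox1 (adjusted p = 0.090) lost its call while Kl (adjusted p = 0.0060) kept it. Kl lost its call when any of 13 arrays was left out, all but 01, 03, 05, 07, 09, 10 and 19. Hmox1 lost its call for 13 arrays, Cyp4b1 for 7, Dusp6 for 6 and Psat1 for 2. The count was 19 without arrays 05 to 08 and fell to 17 without array 16 or 18. The genotype comparisons on the 2 diets share no array but come from 1 fit with shared variances, and in both the repeat arrays of Hyp and normal mice lie in different array sets. Both called 5 of the same probe sets higher, where independent lists of these sizes would share 0.027, and 3 lower, where they would share 0.012.

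**Figure D2:**
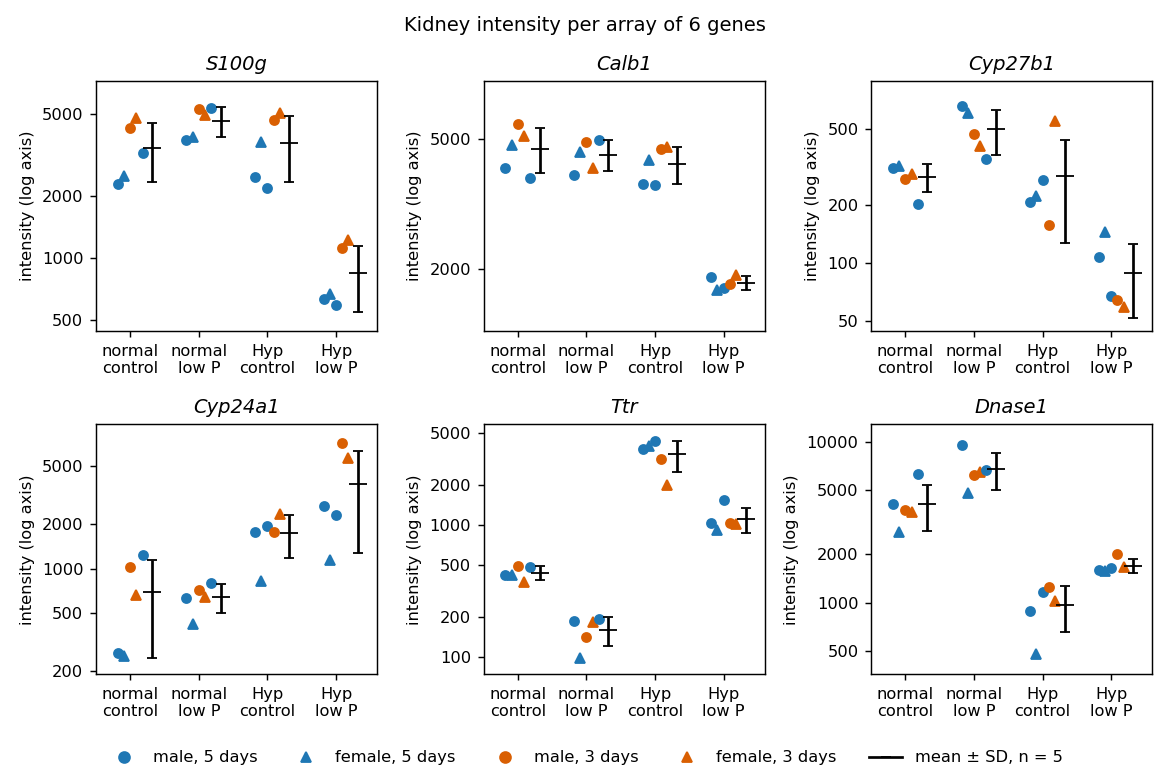
Intensity (log axis) of 6 genes in each array, by group, with colour for days and shape for sex; bars are the mean ± SD of 5 arrays. All 5 Hyp arrays on low phosphate diet lie below the other 15 for S100g (mean 849), Calb1 (mean 1815) and Cyp27b1 (mean 88.7).

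The difference between the diet responses of Hyp and normal mice was tested as an interaction. The probe sets called were all of vitamin D and calcium genes. Recovery on simulated data was low for this test (7.92% of changes of 0.5 and 56.7% of changes of 1), so other differences may be missed. On low phosphate diet S100g went from 3420 ± 1086 to 4617 ± 777 in normal mice and from 3612 ± 1277 to 849 ± 299.8 in Hyp mice (SD, n = 5 each). Calb1 went from 4665 ± 733 to 4478 ± 476 in normal mice and from 4192 ± 538 to 1815 ± 85.5 in Hyp mice (SD, n = 5 each). Cyp27b1 went from 280 ± 46.6 to 499 ± 131 in normal mice and from 283 ± 156 to 88.7 ± 37.1 in Hyp mice (SD, n = 5 each). Limma called 4 probe sets, all with a lower response in Hyp, and 280 had an unadjusted p under 0.05. They were S100g with 2 probe sets (-2.50 ± 0.23 SE, adjusted p = 2.9e-05, and -1.86, adjusted p = 0.0027), Calb1 (-1.13 ± 0.15 SE, adjusted p = 0.0027) and Cyp27b1 (-2.01 ± 0.34 SE, adjusted p = 0.042), with the same sign in all 4 combinations of sex and days. Within the 4 array sets the interaction ran from -3 to -2.06 for S100g, from -1.24 to -0.87 for Calb1 and from -3.04 to -1.36 for Cyp27b1. The vitamin D and calcium list had a lower response in Hyp (14 measured, mean -0.40, adjusted p = 1.3e-05; adjusted p = 0.0053 with an estimated correlation). S100g, Calb1 and Cyp27b1 passed over all probe sets and adjusted over the list alone, and the list's mean was -0.49 to -0.32 within array sets (its median over all arrays was -0.10). Fatty acid oxidation genes had a lower response in Hyp (24 of 30 negative, adjusted p = 0.00037; adjusted p = 0.44 with an estimated correlation) and cholesterol synthesis genes a higher one (12 of 16 positive, adjusted p = 0.0064; adjusted p = 0.30 with an estimated correlation). Phosphate handling and thick ascending limb genes (adjusted p = 0.034 for both; adjusted p = 0.30 for both with an estimated correlation) and interferon-responsive genes (adjusted p = 0.043; adjusted p = 0.77 with an estimated correlation; 0.073 with the array set as a block) had lower responses. Matrix genes (adjusted p = 0.018; 0.60 as the adjusted p with an estimated correlation), endothelial markers (adjusted p = 0.043; 0.31 as the adjusted p with an estimated correlation) and adipocyte genes (adjusted p = 0.034; 0.53 as the adjusted p with an estimated correlation) had higher ones. For fatty acid oxidation the interaction mean was -0.48 and -0.47 in the 5-day array sets and -0.014 and -0.12 in the 3-day sets. Within array sets it was -0.018 to 0.55 for cholesterol synthesis and -0.68 to 0.083 for interferon-responsive genes, so both changed sign in some set. Of the members of these lists other than the vitamin D list, Calb1 passed over all probe sets, and adjusted over the list alone Egf and Msmo1 passed besides. Acot1 (-0.64), Slc34a1 (-0.14), Kl (-0.14) and Cyp24a1 (0.79) did not pass (adjusted p = 1.00 for each). S100g and Calb1 kept their calls without any single array, but Cyp27b1 lost its call when any array except 07, 08, 13, 16, 17 or 20 was left out. With the array set as a block all 4 calls were kept (5 in total, adjusted p = 0.045 for Cyp27b1), and without arrays 05 to 08 the count was 1.

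**Figure D3:**
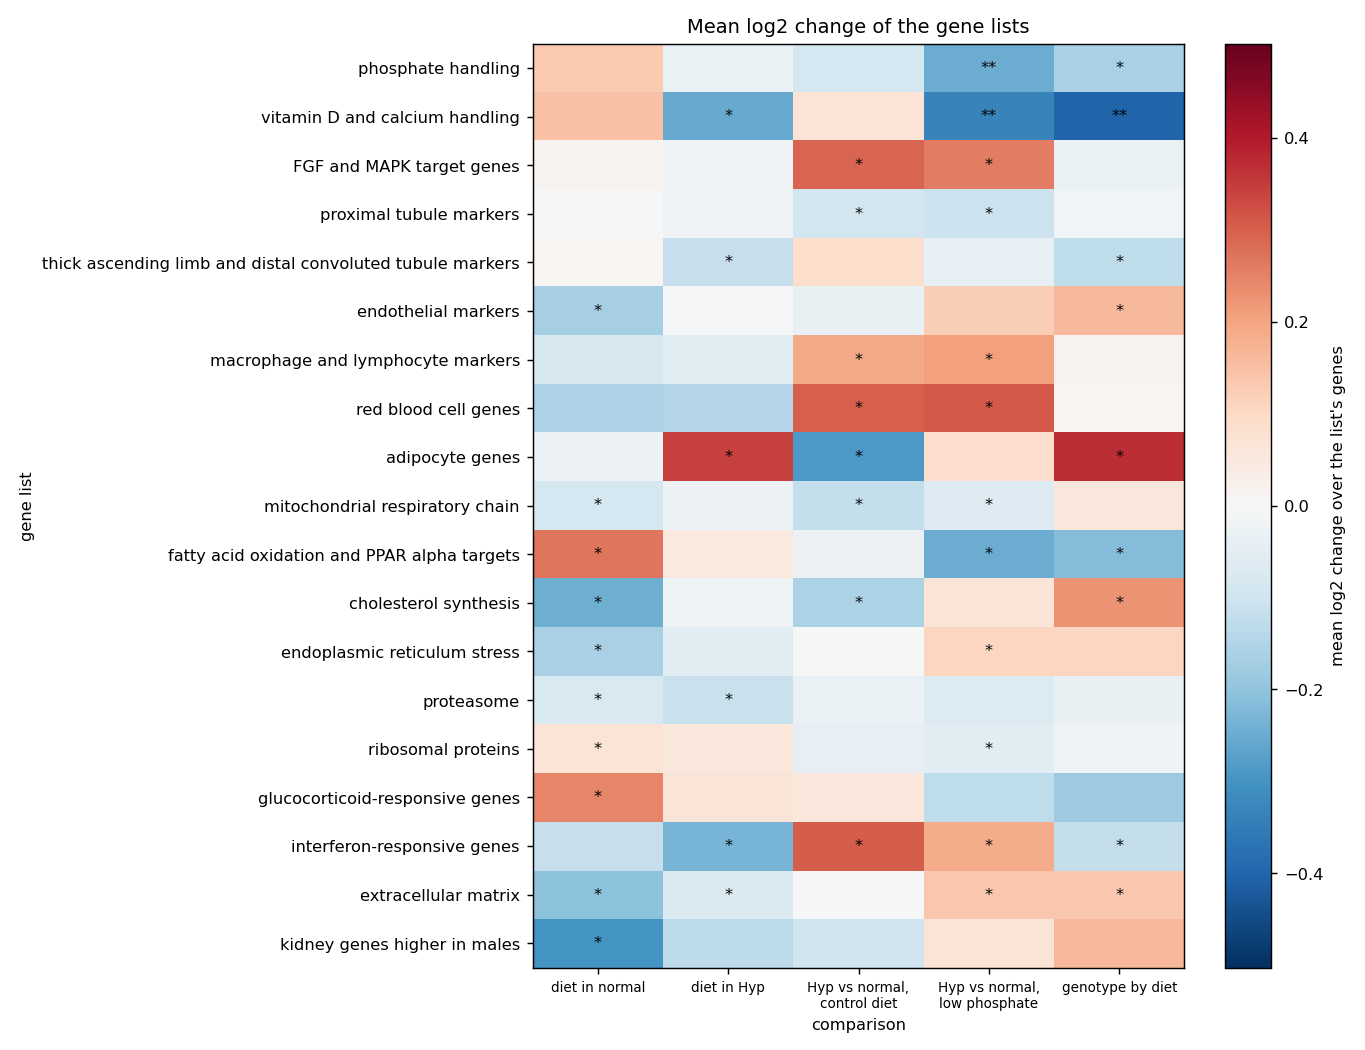
Mean log2 difference over the measured genes of each list (rows) in the 5 main comparisons (columns), as a colour scale; 1 asterisk marks an adjusted p under 0.05 with the preset correlation and 2 asterisks mark calls that also held with an estimated correlation. The vitamin D and calcium list has 2 asterisks for genotype on low phosphate diet (mean -0.33) and for the interaction (mean -0.40).

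Averaged over genotypes, low phosphate diet lowered Ttr (log2 difference -1.42, adjusted p = 1.2e-05), Col5a2 (-0.69, adjusted p = 0.00048), Pck1 (-0.83, adjusted p = 0.0015) and Bcat1, the cytosolic branched-chain aminotransferase (-1.11, adjusted p = 0.0049). It raised Mdk (0.84, adjusted p = 0.00087), Acot1 (0.67) and Dnase1 (0.79, adjusted p = 0.0049). Slc22a6, the organic anion transporter of the proximal tubule, fell (-0.48, adjusted p = 0.0074), as did the secreted chaperone gene Manf (-0.89, adjusted p = 0.018). Cirbp, the cold-inducible RNA-binding protein, rose in the average (0.65, adjusted p = 0.024), with 691 ± 76.3 and 1279 ± 232 on control and low phosphate diet in normal mice and 698 ± 84.1 and 1010 ± 315 in Hyp mice (SD, n = 5 each). Calb1 (-0.62) and S100g (-0.78) passed as well, with responses that differed between genotypes by the interaction test. Limma called 41 probe sets, 15 higher and 26 lower, with 852 at an unadjusted p under 0.05. Of the probe sets called lower in normal mice and in Hyp mice separately, which share no array but come from 1 fit, 2 were the same, Col5a2 and Ttr, where independent lists would share 0.0092. Of those called higher 0 were the same, where independent lists would share 0.0028. Matrix genes fell as a list (adjusted p = 2.0e-05; adjusted p = 0.28 with an estimated correlation), with Col5a2, Col15a1 and Col3a1 past the test over all probe sets and 8 adjusted over the list alone. Proteasome genes were lower (33 of 37 negative, adjusted p = 0.00065; adjusted p = 0.28 with an estimated correlation), as were interferon-responsive genes (adjusted p = 0.00065; adjusted p = 0.40 with an estimated correlation). Fatty acid oxidation genes were higher (adjusted p = 0.0014; adjusted p = 0.40 with an estimated correlation). In all 11 lists were called, 2 higher and 9 lower. The others were endothelial markers, the respiratory chain, the citric acid cycle, cholesterol synthesis, endoplasmic reticulum stress and male-higher kidney genes, all lower, and ribosomal proteins, higher, and none of the 11 held with an estimated correlation (smallest adjusted p = 0.28). Within arrays 01 to 04 the citric acid cycle (0.0024), cholesterol synthesis (0.044), male-higher genes (0.066) and ribosomal proteins (-0.012) had the opposite sign. When array set was a block, 97 probe sets passed, including all 41, against 20 without arrays 05 to 08. Col3a1 lost its call for 18 of the 20 arrays, Col15a1 for 15, Cirbp for 11 and Manf without array 14. The count fell to 25 without array 15 and to 27 without array 14 or 17.

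Averaged over diets, Hyp differed from normal mice at 110 probe sets in limma, 66 higher and 44 lower, with 1299 at an unadjusted p under 0.05. Ttr was higher in Hyp (2.68, adjusted p = 4.5e-10) and Dnase1 lower (-2.01, adjusted p = 4.8e-08). Cyp24a1 was higher (1.86 ± 0.23 SE, adjusted p = 0.00026) and Cyp27b1 lower (-1.09, adjusted p = 0.0026). Kl was lower (-0.47 ± 0.08 SE, adjusted p = 0.0036), as were Pth1r, the parathyroid hormone receptor (-0.61, adjusted p = 0.022), and Fgfr4, an FGF receptor (-0.67, adjusted p = 0.037). Fgfr1, another FGF receptor (-0.05, adjusted p = 0.81), and Vdr, the vitamin D receptor (0.27, adjusted p = 0.36), did not pass. Alpl was lower (-0.58, adjusted p = 0.023), whereas Slc34a1, at 13810 ± 1874 in normal and 11500 ± 1437 in Hyp mice on control diet (SD, n = 5 each), did not pass (-0.33, adjusted p = 0.055). Dusp6 (0.78, adjusted p = 0.00043), Ier3 (0.58, adjusted p = 0.0042) and Cyp4b1 (1.34, adjusted p = 0.0036) were higher, and Slc2a2 (-0.34, adjusted p = 0.012) and Slc37a4 (-0.53, adjusted p = 0.00043) lower. All called genes named here had the same sign in all 4 combinations of sex and days, and within array sets Kl ran from -0.54 to -0.40 and Cyp24a1 from 1.48 to 2.43. Phosphate handling genes (mean -0.17, adjusted p = 0.00022), vitamin D and calcium genes (mean -0.13, adjusted p = 0.0029) and FGF and MAPK targets (8 of 8 positive, adjusted p = 0.00055) were called, the first 2 lower and the last higher. All 3 held at an adjusted p of 0.044 with an estimated correlation. Kl, Pth1r, Alpl and Fgfr4 of the phosphate list and Dusp6 and Ier3 of the FGF list passed over all probe sets, and Slc34a1 and Spred2 joined them adjusted over the list alone. Macrophage and lymphocyte markers (16 of 18 positive, adjusted p = 0.00049; adjusted p = 0.054 with an estimated correlation) and red blood cell genes (5 of 5 positive, adjusted p = 0.0029; adjusted p = 0.073 with an estimated correlation) were higher in Hyp. Interferon-responsive genes were higher as well (25 of 27 positive, adjusted p = 4.1e-06; adjusted p = 0.26 with an estimated correlation). Proximal tubule markers were lower (24 of 27 negative, adjusted p = 9.8e-05; adjusted p = 0.073 with an estimated correlation). The gluconeogenesis and ammoniagenesis list was lower (adjusted p = 0.030; adjusted p = 0.084 with an estimated correlation), with Slc37a4 and Slc2a2 lower and G6pc higher over all probe sets. Its call and that of ribosomal proteins were lost with the array set as a block (adjusted p = 0.070 for both). So was the call of G6pc (0.29, adjusted p = 0.11), which 10 of the 20 arrays also ended when left out singly. The respiratory chain (adjusted p = 1.4e-05; 0.27 as the adjusted p with an estimated correlation), fatty acid oxidation (adjusted p = 0.0011; 0.36 as the adjusted p with an estimated correlation) and ribosomal proteins (adjusted p = 0.019; 0.30 as the adjusted p with an estimated correlation) were lower. Their means within array sets reached 0.0064, 0.00094 and 0.025, against the direction of the lists. The 5′ and middle 18S control probe sets were lower in Hyp in this average (-0.78 and -1.11). It includes the control diet arrays, so this is no separate finding. On low phosphate diet alone, 0 control probe sets were called between genotypes. Both probe sets were dim, at 84.42 ± 30.85 and 40.96 ± 30.79 in Hyp against 185.8 ± 116.3 and 141.7 ± 90.48 in normal mice (SD). The Hyp mean of the middle probe set lay close to the offset added before log2. With the array set as a block 95 probe sets passed, 67 of them among the 110. Pth1r (-0.48, adjusted p = 0.10) and Fgfr4 (-0.53, adjusted p = 0.13) lost their calls while Kl, Alpl and Cyp24a1 kept theirs. Left out singly, array 02 ended the calls of Pth1r, Alpl and Fgfr4, array 12 ended those of Pth1r and Fgfr4, and Fgfr4 lost its call for 12 of the 20 arrays. The count was 60 without arrays 05 to 08, 72 without arrays 09, 10, 19 and 20 and 63 without array 02.

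Females differed from males at 1304 probe sets, 624 higher and 680 lower in females, with 2839 at an unadjusted p under 0.05 in limma. Cyp4b1, at 3357 ± 2509 in 8 female and 13570 ± 5555 in 12 male arrays (SD), was lower in females (-2.17, adjusted p = 1.8e-05). Slc22a30, an organic anion transporter (-2.99, adjusted p = 5.6e-06), Inmt (-2.02, adjusted p = 2.8e-07) and Fmo5 (-2.00, adjusted p = 0.0011) were lower in females, and Abcc3, an organic anion efflux pump, was higher (2.06, adjusted p = 0.0011). Kidney genes known to be higher in males were lower in females as a list (14 measured, adjusted p = 0.0036; adjusted p = 0.66 with an estimated correlation), with 9 lower and 2 higher over all probe sets. The 2 higher members were Abcc3 and Gsta2, a glutathione transferase (0.79, adjusted p = 0.00020). Smooth muscle and fibroblast markers were higher (17 measured, adjusted p = 0.039; adjusted p = 0.66 with an estimated correlation), among them Dcn (0.46) and Lum (0.39), both genes of matrix proteoglycans. Col1a1, a collagen chain, was called lower in females (-0.54), the opposite direction. The list lost its call without arrays 05 to 08 (adjusted p = 0.46). Respiratory chain genes were lower (mean -0.11, adjusted p = 0.029; adjusted p = 0.73 with an estimated correlation). Of the 64, 10 were lower over all probe sets and 10 adjusted over the list alone, Ndufb3 (-0.58) and Ndufv1 (-0.38) among them. Of the 8 female arrays, 05 to 08 had the lowest correlations with the other arrays. Without these 4 the count was 17, the respiratory chain list turned higher (0.015) and Col1a2, a collagen chain, turned from 0.79 to -0.08. Arrays 05 to 08 are all the 5-day female arrays, so that fit compares the sexes at 3 days alone. Ndufb3 lost its call when any of these 4 arrays was left out. Over 30 alternatives, Slc22a30 and Inmt kept their calls in all, Cyp4b1 and Abcc3 lost theirs in 1 and Fmo5 and Gsta2 in 2. Dcn and Lum lost theirs in 3, at differences down to 0.18 and 0.21. Within 3-day arrays, which rest on the same comparison of the sexes, the count was 46. Each array set holds 1 sex, so sex and array set cannot be separated.

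Mice fed for 5 and for 3 days differed at 2782 probe sets, 1410 higher and 1372 lower at 5 days, with 3835 at an unadjusted p under 0.05 in limma. Car3, a carbonic anhydrase abundant in adipose tissue (1.81, adjusted p = 0.0021), and Cidea (1.56) and Thrsp (1.37), both genes of lipid storage and synthesis, were higher at 5 days. Fasn, fatty acid synthase (0.77, adjusted p = 0.0074), Acly, ATP citrate lyase (0.66), and Scd1, the fatty acid desaturase (0.69, adjusted p = 0.0052), were higher as well. Over single arrays Car3 ran from 98.7 to 2010 and Adipoq, an adipocyte gene, from 186 to 1327. The adipocyte list was not called between durations, and the share of fat tissue in the pools was not tested. Fatty acid synthesis was higher as a list (13 measured, adjusted p = 0.049; adjusted p = 0.52 with an estimated correlation), with 4 members past the test over all probe sets and 4 adjusted over the list alone. Respiratory chain genes (adjusted p = 0.022; adjusted p = 0.55 with an estimated correlation) and proteasome genes (adjusted p = 0.028; adjusted p = 0.52 with an estimated correlation) were lower at 5 days. Over all probe sets 20 of 64 respiratory chain genes were lower and 4 higher, and 10 of 37 proteasome genes were lower and 2 higher. Actb, cytoplasmic actin (-2.18, adjusted p = 0.0021), and Cyp24a1 (-0.92, adjusted p = 0.012) were lower. Each array set holds 1 duration, so days and array set cannot be separated. The count was 24 without arrays 05 to 08, 5 in male arrays alone and 2850 in female arrays alone. Arrays 05 to 08 are all the 5-day female arrays, so the fit without them compares durations in males alone, as the male fit does. Each of the 8 genes named here lost its call without arrays 05 to 08 (adjusted p = 0.089 for Car3 to 0.34 for Cyp24a1) and in male arrays alone (adjusted p = 0.18 to 0.43), and the log2 difference of Acly was 0.36 in both. All 8 kept their direction in every alternative. Their smallest differences there were 1.18 for Car3, 1.20 for Cidea, 0.95 for Thrsp, 0.56 for Fasn, 0.36 for Acly and 0.63 for Scd1. Those of Actb and Cyp24a1 were -1.78 and -0.56. The 3 lists lost theirs without arrays 05 to 08 as well (adjusted p = 0.17 to 0.24).

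Whether diet and genotype act differently by sex or by days was tested as 3 further interactions, and limma called 0 probe sets in each. At an unadjusted p under 0.05 there were 206 for diet by sex, 380 for genotype by sex and 187 for diet by days. Without array 16, diet by sex called 2, and no other alternative run on these 3 gave a count above 0. The smallest p for diet by sex was at Banp (0.83, adjusted p = 1.00), and Plekho1 (1.32, adjusted p = 0.98) was among the smallest for genotype by sex. Interferon-responsive genes had a lower diet response in females, with 24 of 27 negative (adjusted p = 4.0e-05; adjusted p = 0.76 with an estimated correlation). Within array sets, with 1 array per group, their mean diet difference was -0.271 in males and -0.287 in females at 5 days. At 3 days it was -0.051 in males and -0.405 in females, so the sexes differed in the 3-day sets alone. Vitamin D and calcium genes (adjusted p = 0.036; adjusted p = 0.33 with an estimated correlation) and proximal tubule markers (adjusted p = 0.025; adjusted p = 0.50 with an estimated correlation) had lower diet responses in females too. The genotype difference of respiratory chain genes was higher in females (adjusted p = 0.013; adjusted p = 0.98 with an estimated correlation), and no list was called for diet by days.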

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

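Of the tests below, those of the position of arrays 19 and 20 along the days axis, of the sign of the 804 probe sets and of the array-set block for genotype were chosen after their results were seen, and the splits balanced over sex and days were added after the other splits had been seen; the other tests were not.

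The diet response differed between Hyp and normal mice, by a test of the interaction, for S100g (-2.50, and -1.86 at a second probe set), Calb1 (-1.13) and Cyp27b1 (-2.01). Among gene lists it differed for vitamin D and calcium handling (mean -0.402), phosphate handling (-0.163), thick ascending limb and distal convoluted tubule markers (-0.129), fatty acid oxidation (-0.219) and interferon-responsive genes (-0.118), all lower in Hyp. It was higher in Hyp for endothelial markers (0.163), adipocyte genes (0.373), cholesterol synthesis (0.225) and extracellular matrix (0.134), and only the vitamin D and calcium list kept its call with an estimated correlation. The diet response differed between the sexes for vitamin D and calcium handling (-0.145), proximal tubule markers (-0.121) and interferon-responsive genes (-0.285), and the genotype difference did for the respiratory chain (0.12). None of these 4 calls held with an estimated correlation. For interferon-responsive genes the mean diet difference within array sets differed between the sexes at 3 days (-0.051 in males, -0.405 in females). At 5 days it hardly differed (-0.271 in males, -0.287 in females).

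A single array lay far from the other 4 of its group in 14 of 224 groups examined, where chance alone gives about 1 in 20; the gap to the nearest array is given as a share of the group's range. In normal mice on control diet these were Bex4 on array 15 (1038 against 712 to 725, share 0.961) and Slc2a2 on array 11 (3558 against 2836 to 3016, share 0.751). In Hyp mice on control diet they were Cyp27b1 on array 17 (554 against 159 to 271, share 0.716), Kl on array 03 (3919 against 4648 to 4938, share 0.715) and Prom1 on array 07 (4399 against 2584 to 3082, share 0.726). In Hyp mice on low phosphate diet they were Dnase1 on array 14 (1999 against 1582 to 1665, share 0.803) and Htr3a on array 08 (449 against 209 to 229.7, share 0.912). Array 10 of the same group stood apart for Kl (5958 against 4460 to 4708, share 0.834), Pdzk1 (8185 against 5515 to 6234, share 0.731) and Ttr (1535 against 916 to 1036, share 0.806). Arrays 05, 06 and 08 had low median correlations with the other arrays (0.934, 0.914 and 0.895, shares 0.781, 0.849 and 0.726), and array 07 had a high actin 3′ to 5′ ratio (2.55 against 1.23 to 1.61, share 0.714).

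Ttr was higher and Dnase1 lower in Hyp mice on both diets. Liver RNA in the Hyp pools would raise abundant liver transcripts that are dim in kidney at about the size of the Ttr difference. A contribution of that size was argued against by a median log2 difference of 0.286 over 13 liver genes (95% interval 0.20 to 0.387). The interval comes from resampling genes and does not measure the spread between pools. All of these genes but Kng1 had a positive difference, so a smaller amount of liver RNA is not excluded. Alb was at 986 and 0.39, and 0 of the 13 were called. Kng1 (-0.02) was already bright at 7831, so a small addition could not move it much and it decides little. Pancreas RNA in the Hyp pools, which would bring pancreas genes up with Ttr, was argued against by a median of 0.0412 over 7 pancreas genes (95% interval 0.0251 to 0.337). That interval too comes from resampling genes, and Cela1 (-0.13), at 2689, has the same limit as Kng1. A difference between array sets was argued against, since the smallest Ttr difference within a set was 2.29 averaged over diets (2.32 on control and 2.26 on low phosphate diet). An effect of the Hyp genotype on both genes, not tested beyond the comparison itself, stays open as a hypothesis.

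At 2782 probe sets 5-day arrays differed from 3-day arrays. Days on diet as the whole cause were argued against by arrays 19 and 20, which are 5-day arrays but lay at 0.133 and 0.2816 on the 5-day against 3-day axis of the other arrays, where 5-day arrays 01 to 10 ran from 0.678 to 1.51 and 3-day arrays from -0.618 to 0.688. Lower RNA quality of the 5-day arrays as the whole cause was argued against by a direct comparison. Between 5-day arrays 01 to 04 and 3-day arrays 11 to 14, 1305 probe sets were called. There the 5-day arrays had the lower actin ratios (1.22 to 1.27 against 1.496 to 1.98). These sets differ in that ratio themselves, so the count does not show how much quality contributes. Of the 804 also called over all arrays, 803 had the same sign. That fit holds these arrays too, so the agreement in sign adds little. Without arrays 05 to 08, which had the lowest correlations with the other arrays, 24 probe sets differed between durations. These are all the 5-day female arrays, so that fit compares durations in males alone. It cannot separate the quality of these arrays from their sex or from the smaller number of arrays. A part of lower quality in those 4 arrays stays open. The array set and an effect of days on part of the probe sets cannot be told apart, since each set holds 1 duration, and stay open.

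Hyp mice differed from normal mice at 110 probe sets averaged over diets. The male 5-day repeat arrays of the genotypes sit in different array sets (09 and 10 for Hyp, 19 and 20 for normal mice), but 67 of the 110 stayed called with the array set as a block, and without those 4 arrays 72 were called, 50 of them among the 110, which argues against those sets as the whole cause. For the probe sets that lost their calls the part of the array sets stays open. An effect of genotype, as the design names it, stays open for all 110.

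Other splits of the arrays were drawn for each count of called probe sets, 100 with the real one. For diet in normal mice (16, highest other 1), diet in Hyp mice (13, highest other 2), genotype on control diet (21, highest other 2) and on low phosphate diet (31, highest other 0), the genotype by diet interaction (4, highest other 2), diet averaged (41, highest other 2) and genotype averaged (110, highest other 2), 1 split, the real one, reached the real count. These splits were not balanced over sex and days as the real groups are, so splits that keep each group's number of arrays in each of the 4 strata were run as well. Among all 24 such splits only the real one reached the real count for diet in normal mice (highest other 1) and in Hyp mice (0). The same held for genotype on control (1) and low phosphate diet (0). A share of 1 in 24 is the smallest these splits can give, so they make chance unlikely for each count but cannot exclude it. For diet averaged (highest other 5) and genotype averaged (highest other 4), the real split alone of 100 drawn from 1152 reached the real count. Chance as the source of those whole counts is argued against, which says nothing about single probe sets. For the interaction 4 of 100, the real one included, reached the real count of 4, and 13 of the others had calls. Chance cannot be excluded for that count. The highest other called 41. That split exchanged the diets of every normal array, so it measures diet averaged over genotypes and points to that structure. The balanced splits do not keep the array sets of arrays 09, 10, 19 and 20 in balance.

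For sex 1 split, the real one, reached 1304 (highest other 72), and for days 2 splits reached 2782, the other one calling 2989. That split set arrays 02, 03 and 05 to 10 apart and so follows the structure of the array sets. Each set holds 1 sex and 1 duration and the splits moved single arrays, so for these comparisons they exclude only a chance assignment of single arrays, not a difference between sets, and no value within a set can be had. For diet by sex (real count 0, highest other 1023), genotype by sex (0, highest other 98) and diet by days (0, highest other 2), all 100 splits reach a count of 0 by construction, so they say nothing about chance. The splits with 1023 and 98 calls point to a structure of the samples.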

How the results depend on the processing

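The alternatives with the array set as a block, with array weights and without arrays 05 to 08 or 09, 10, 19 and 20 were chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers, and the array set, inferred from the order of the numbers, was used as a block instead. Signal over background limits dim genes, Phex among them, and the cause of a change was not tested except where fewer arrays were fitted.

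Alternatives were run on 144 called values, a gene counting once in each comparison that called it. Of these 4779 alternatives, 3520 kept direction and call and 1257 kept direction and lost the call. The 2 that reversed were both Col1a2 between the sexes (0.79 in the reported fit). It was -0.078 without arrays 05 to 08 and -0.078 in 3-day arrays, fits that compare the sexes at 3 days alone. The respiratory chain list reversed between the sexes without arrays 05 to 08 (0.015). Of 11563 alternatives on 352 uncalled values, 102 became called in the same direction, 222 changed sign without a call and 0 were called with the opposite sign. An offset of 1 and quantile normalization left every count within 1.5 times its reported value.

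Counts are given in the order diet in normal mice (reported 16), diet in Hyp mice (13), genotype on control diet (21), genotype on low phosphate diet (31), interaction (4), diet averaged (41), genotype averaged (110), sex (1304) and days (2782), and only those that moved by over 1.5 times. Without a filter diet in normal mice gave 10, and with a filter at the median it gave 33 and diet averaged 62. Trend and robust moderation gave 29 for diet in normal mice and 49 for genotype on low phosphate diet. Without covariates the counts were 5, 6, 5 and 9 for the first 4 comparisons, 16 for diet averaged and 28 for genotype averaged. With only the 2 groups compared the first 4 were 3, 4, 2 and 11.

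In male arrays only they were 0, 3, 2, 9, 1, 2 and 12 for the first 7 and 5 for days. In female arrays only they were 0, 0, 0, 0, 0 and 0 for the first 6 and 5 for genotype averaged. In 5-day arrays only they were 1, 4, 2, 6, 1, 2 and 3 for the first 7 and 2218 for sex. In 3-day arrays only they were 0, 2, 0, 4, 0, 0 and 6 for the first 7 and 46 for sex. These fits have fewer arrays.

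With the array set as a block diet in normal mice gave 58 and diet averaged 97. Without arrays 09, 10, 19 and 20 diet in normal mice gave 8, diet in Hyp mice 6, genotype on control diet 13, genotype averaged 72 and sex 530. Without arrays 05 to 08 the counts were 6, 6, 3, 19, 1, 20, 60, 17 and 24. Array weights gave 86 for diet in normal mice, 55 and 65 for genotype on control and low phosphate diet, 97 for diet averaged, 184 for genotype averaged and 366 for sex. Of 77 list calls, 6 held with an estimated correlation, 57 with quantile normalization and 61 with the mean of a gene's probe sets. Without arrays 09, 10, 19 and 20, 63 of the 77 held. In the comparisons where these could be run, 58 of 67 held with the array set as a block and 54 of 73 without arrays 05 to 08. Quantile normalization ended the calls of the 3 lists between durations (adjusted p = 0.056 each) and of ribosomal proteins for diet in normal mice (adjusted p = 0.085), among others, and turned no list's direction.

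Leaving out each array in turn gave 5 to 19 for diet in normal mice, and arrays 01, 04, 10, 13 and 18 each gave 10, 05 gave 9, 06 and 16 gave 8, 11 and 15 gave 6 and 02 gave 5. Diet in Hyp mice ran from 6 to 15, with 6 without 13 or 14, 7 without 04, 09, 17 or 18 and 8 without 07 or 08. Genotype on control diet ran from 7 to 25, with 7 without 13, 8 without 03 or 05, 9 without 01, 07 or 17, 10 without 09 or 19 and 12 without 15. Genotype on low phosphate diet ran from 17 to 35, with 17 without 16 or 18, 19 without 02, 08 or 14 and 20 without 04. The interaction gave 3 to 4. Diet averaged ran from 25 to 45, with 25 without 15 and 27 without 14 or 17. Genotype averaged ran from 63 to 100, with 63 without 02, 69 without 10, 70 without 12 and 72 without 13. Sex ran from 429 to 1603, with 621, 429, 655 and 520 without 05, 06, 07 and 08. Days ran from 1964 to 3195. Diet by sex gave 0 to 2, the 2 without array 16, and genotype by sex and diet by days gave 0 to 0.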

Other observations

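The amino acid catabolism list was not called in any comparison, yet a member passed the test. Bcat1, the cytosolic branched-chain aminotransferase, went from 1071 ± 544 to 460 ± 110 in normal mice and from 1202 ± 339 to 509 ± 132 in Hyp mice on low phosphate diet (SD, n = 5 each). Slc51a, the organic solute transporter subunit of bile acid efflux, was 992 ± 497 and 418 ± 29.4 in normal mice and 816 ± 336 and 499 ± 132 in Hyp mice on control and low phosphate diet (SD, n = 5 each), with an averaged log2 difference of -0.83 (limma adjusted p = 0.033). Both genes fell in the average over genotypes, where Bcat1 kept its call without any single array and Slc51a lost its call in 14 of 20. Cyp4a14, a fatty acid hydroxylase induced through PPAR alpha, rose in the average (0.84, limma adjusted p = 0.047), and its call was lost in 17 of 20. The list of genes named for higher expression in males held Gsta2, which was higher in females here (0.79), and among the members that fell on low phosphate diet adjusted over the list alone it stood with Odc1, Slc22a6 and Cyp4b1.

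Fabp3, the heart-type fatty acid binding protein, was lower in Hyp mice (-0.79, limma adjusted p = 0.015; -0.51 with the array set as a block), at 457 ± 236 and 510 ± 224 on control and low phosphate diet against 834 ± 335 and 874 ± 355 in normal mice (SD, n = 5 each). Ces1g, a carboxylesterase, was higher in Hyp (1.80, limma adjusted p = 0.0023), at 604 ± 507 and 242 ± 182 against 136 ± 127 and 23.4 ± 24.0 (SD, n = 5 each). It was dim, with the last mean under the offset of 38, and its difference within array sets ran from 0.50 in arrays 05 to 08 to 2.79. Serpina6, corticosteroid-binding globulin, ran from 25 to 8928 over single arrays, and was higher in females (2.52, limma adjusted p = 0.038), a call lost when any of 12 arrays was left out. Among control probe sets, the 3′ pyruvate carboxylase probe set was lower in Hyp (-0.56, limma adjusted p = 0.030; -0.31 with the array set as a block), at 2558 ± 1166 in 10 Hyp arrays and 3628 ± 1213 in 10 normal arrays (SD).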
